A study of Homo sapiens with 18 samples.

How the data were processed

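Total RNA of 18 samples was hybridised to Affymetrix Human Gene 1.0 ST arrays, biotin-labelled per the labels. The deposited values are log2 expression values for 33297 probe sets, made by the authors with RMA per the submitters' processing notes, which combines background correction, quantile normalization and a summary over probes. The RMA software version and any genome build are not given in the sources used here. The log2 scale was read from the values, and it is not stated whether all arrays were normalized together, though the array medians lie close together. RMA compresses differences at the dim end, so changes of dim genes are understated. No detection calls were used, so a low value is not read as absence.

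Groups came from the sample titles, which name the line, the insert and a replicate number. Gene names came from the platform annotation supplied with the values: 19460 probe sets had 1 symbol, 1754 had several and 12083 were not listed there. Symbols were updated through gene IDs to the GRCh38.p14 gene table, which matched 19429, and no coordinates were used beyond the order of neighbouring genes. Genes with over 1 probe set (769) were represented by the one with the highest mean, leaving 18417 genes. Probe sets with several symbols or none were not used for named genes. All value columns were mapped to samples, and no pair of columns was identical.

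Differences were computed with limma 3.58.1 in R 4.3.3, with a model of 6 group means over all 18 arrays, 12 residual degrees of freedom and the Benjamini-Hochberg adjustment over genes. A gene counted as changed at an adjusted p under 0.05 and an absolute log2 change of at least 1, which is 2-fold. Differences between lines were tested as the difference of fold changes in the same model. The 34 gene lists, with 589 of 646 entries measured, were fixed before the data were examined, as were the tests and the rule for named genes. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, whose directional p asks whether a list moves one way on balance and does not compare it with other genes. List p-values were adjusted over the 34 lists in each comparison. Counts of list members that rose or fell use the adjusted p without the 2-fold limit. They are to be read beside the share of all genes that passed by the same rule, in either direction, given with each comparison.

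The text could name SNAI1, TWIST1, CDH1, EPCAM, CDH2, VIM, FN1 and ZEB1 in any comparison. It could also name the 8 largest rises and 8 largest falls per comparison with vector, 5 of each in the other comparisons and among genes shared by all 4, and up to 4 members of each list. The largest changes were taken among genes with adjusted p under 0.05 whose groups did not overlap, which chance gives for 10% of genes at 3 against 3. Genes outside this rule appear only in the closing section, where this is said.

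Replicate numbers are shared by the groups. The correlation of deviations from group means by number was checked for the pairs of groups compared with each other here. Among these it was over 0.1 for all numbers only between MCF10A Snail and the arrays labelled MCF10A Twist (0.45, 0.37 and 0.11). Other pairs, such as HMLE Twist with the arrays labelled MCF10A Twist, were not checked. The numbers were taken to pair the MCF10A Snail and labelled Twist arrays, and a fit with the number as a block was run for all comparisons. Comparisons with the same vector arrays share their chance values, so 50 simulations of unchanged groups gave the correlation and covariance to expect with no effect. Alternatives covered quantile normalization, median centring, array weights, trended and robust variance, the mean of probe sets, a filter on dim genes, a subset of groups in the fit, replicate blocks, other thresholds and set tests, and each array left out in turn. After the data were seen, lists without SNAI1 and TWIST1 and other uses of the arrays labelled MCF10A Twist were added. The fit was tested on simulated data for HMLE Snail against vector with 18417 genes: of 50 genes changed by 1.5 on the log2 scale, 100% were called, and none of the 50 changed by 0.5 passed the 2-fold limit. Figures were drawn with matplotlib 3.10.9.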

Results

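Gene expression was measured in 18 samples of total RNA from a pair of non-tumorigenic human mammary epithelial lines. HMLE cells are mammary epithelial cells immortalised with telomerase and viral T antigens, and MCF10A is a spontaneously immortalised mammary epithelial line. Each line carried an empty vector, Snail or Twist, as stable clones per the labels, with 3 arrays in each of the 6 groups. Snail (gene SNAI1) and Twist (gene TWIST1) are transcription factors that repress epithelial genes and drive epithelial-mesenchymal transition (EMT). The comparisons ask what each factor changed in each line, how the factors differed, and how the lines differed. Array medians lay between 7.698 and 7.793 on the log2 scale, and correlations between replicates across probe sets between 0.99 and 0.997. The number of arrays limits the precision. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. Levels are given as log2 mean ± SD of 3 arrays. Changes are given as log2 difference ± SE from limma, and a gene rose or fell where its adjusted p was under 0.05.

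SNAI1 followed the labels of the Snail arrays. In HMLE it stood at 7.39 ± 0.14 with vector and at 12.53 ± 0.01 with Snail, a rise of 5.14 ± 0.09 (adjusted p = 3.8e-17). In MCF10A it stood at 8.32 ± 0.14 with vector and 12.49 ± 0.07 with Snail, a rise of 4.17 ± 0.09 (adjusted p = 3.04e-14). In the Twist arrays SNAI1 differed from vector by 0.13 ± 0.09 in HMLE (adjusted p = 0.281) and by -0.07 ± 0.09 in the arrays labelled MCF10A Twist (adjusted p = 0.565). TWIST1 was already at 9.69 ± 0.01 in HMLE vector and 10.07 ± 0.09 in MCF10A vector arrays. It rose by 1.8 ± 0.07 in HMLE Twist and by 0.92 ± 0.07 in the arrays labelled MCF10A Twist. It also rose with Snail, by 1.12 ± 0.07 in HMLE and by 0.24 ± 0.07 in MCF10A. Each factor had a single probe set, and the labels do not give the species or sequence of the constructs.

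The 3 arrays labelled MCF10A Twist did not carry the 9p21 pattern of the other MCF10A arrays. MTAP, a methionine salvage enzyme next to CDKN2A in a region deleted in MCF10A, stood at 5.98 ± 0.36 in MCF10A vector and 6.02 ± 0.15 in MCF10A Snail arrays. It stood at 10.8 ± 0.03 in the arrays labelled MCF10A Twist, and at 10.26 ± 0.04, 9.83 ± 0.02 and 10.1 ± 0.11 in HMLE vector, Snail and Twist arrays. The cell cycle inhibitors CDKN2A and CDKN2B were higher in the arrays labelled MCF10A Twist than in MCF10A vector arrays, by 2.41 ± 0.08 and 2.55 ± 0.15. These 3 genes formed a list for line identity, which rose in this comparison (camera adjusted p = 0.0012) and held with an estimated correlation (adjusted p = 0.0142). Every direction drawn below from the arrays labelled MCF10A Twist carries this limit, and all of them keep their label as a name.

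**Figure D1:**
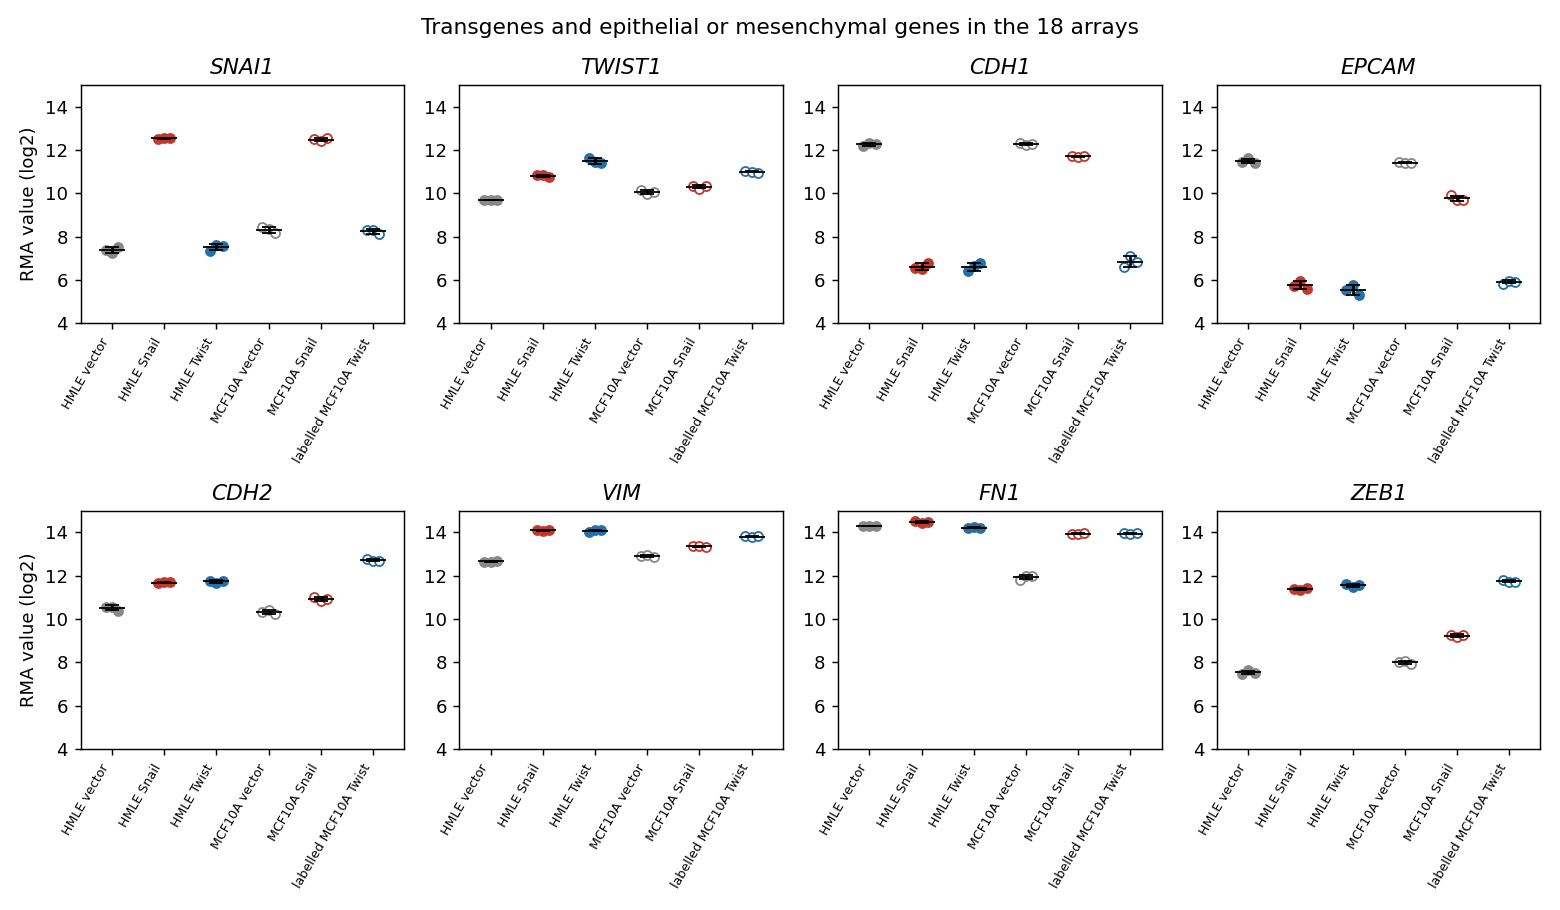
RMA values (log2) of 8 genes in the 18 arrays, 3 per group; circles are arrays, filled for HMLE and open for MCF10A, and black bars are the mean and SD. CDH1 lies near 12.27 in both vector groups, at 6.62 with Snail or Twist in HMLE and at 11.7 with Snail in MCF10A.

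Snail in HMLE was followed by a loss of epithelial adhesion genes and a gain of matrix genes. The adherens junction cadherin CDH1 fell by 5.64 ± 0.11, or 49.9-fold, and the epithelial adhesion molecule EPCAM fell by 5.72 ± 0.11. The largest falls included the cytokine IL1A (-6.38 ± 0.1), the vesicle protein MAL2 (-6.26 ± 0.11), the desmosomal cadherin DSC3 (-6.2 ± 0.13), the integrin ITGB6 (-6.17 ± 0.08) and the cadherin CDH3 (-5.68 ± 0.07). The largest rises included the basement membrane protein NID1 (6.32 ± 0.11), the adenylate kinase AK5 (6.29 ± 0.21), the pentraxin PTX3 (5.73 ± 0.13), the proteoglycan DCN (5.38 ± 0.06) and the lysophospholipase ENPP2 (5.26 ± 0.09). The zinc finger repressor ZEB1 rose by 3.85 ± 0.06, vimentin (VIM) by 1.44 ± 0.04 and N-cadherin (CDH2) by 1.17 ± 0.07. Fibronectin (FN1), already at 14.3 ± 0.01 with vector, rose by 0.18 ± 0.05. In all, 1635 of 18417 genes changed at least 2-fold, 822 up and 813 down. By adjusted p alone, the rule of the list counts below, 47.71% of all genes changed in either direction.

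Of 6 epithelial gene lists 5 fell in HMLE with Snail. Of 16 genes for epithelial surface and trafficking, 16 fell (16 adjusted over the list alone, camera adjusted p = 6.09e-16), among them the antiprotease SLPI (-4.62 ± 0.09) and the recycling GTPase RAB25 (-4.37 ± 0.09). Of 16 desmosome and hemidesmosome genes, 14 fell and 1 rose (14 and 1 adjusted over the list alone, adjusted p = 6.72e-11), including DSC2 (-5.5 ± 0.09) and the laminin receptor ITGA6 (-4.6 ± 0.05). All 5 basal keratins measured fell (5 adjusted over the list alone, adjusted p = 1.5e-05), with KRT5 at -4.92 ± 0.08 and KRT14 at -4.17 ± 0.09. Of 19 junction and polarity genes 15 fell (15 adjusted over the list alone, adjusted p = 5.89e-10), and 11 of 14 epithelial transcription and splicing regulators fell while 1 rose (11 and 1 adjusted over the list alone, adjusted p = 7.06e-05). Those regulators included GRHL2 (-4.19 ± 0.06) and EHF (-4.92 ± 0.12), which maintain epithelial programmes, while GATA3 rose by 2.4 ± 0.07. These 5 calls held with an estimated correlation. Luminal keratins and mammary luminal markers were not called (4 fell and 1 rose of 13, 4 and 1 adjusted over the list alone, adjusted p = 0.308).

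Matrix and mesenchymal lists rose with Snail in HMLE. Of 27 collagen and matrix genes, 23 rose and 2 fell (24 and 2 adjusted over the list alone, camera adjusted p = 6.32e-15), with biglycan (BGN) at 5.03 ± 0.08 and fibrillin 1 (FBN1) at 4.97 ± 0.07, against a fall of the microfibril gene MFAP5 by 5.28 ± 0.07. Of 20 mesenchymal markers 17 rose and 1 fell (17 and 1 adjusted over the list alone, adjusted p = 5.55e-11), and of 15 fibroblast markers 13 rose and 2 fell (13 and 2 adjusted over the list alone, adjusted p = 1.34e-09), including PRRX1 (4.83 ± 0.12) and COL1A2 (4.6 ± 0.08). These calls also held with an estimated correlation. The fibroblast list shares 7 genes with the matrix list, and the endothelial list (2 rose, 1 fell of 13; 2 and 1 adjusted over the list alone, adjusted p = 0.668) and the leukocyte list (4 rose, 1 fell of 14; 4 and 1 adjusted over the list alone, adjusted p = 0.658) were not called.

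Some further lists were called in HMLE with Snail only under the preset correlation. Of 28 cell cycle genes, 26 fell (26 adjusted over the list alone, adjusted p = 1.99e-10, and adjusted p = 0.176 with an estimated correlation), with the spindle checkpoint kinase BUB1B at -1.11 ± 0.07 and the ribonucleotide reductase subunit RRM2 at -1.03 ± 0.06. Of 18 p53 targets, 13 rose and 3 fell (13 and 3 adjusted over the list alone, adjusted p = 0.00025, and adjusted p = 0.195 with an estimated correlation), including GDF15 (2.31 ± 0.07) and TP53INP1 (2.04 ± 0.08). Of 19 mesenchymal growth factor receptors and ligands, 13 rose and 5 fell (13 and 5 adjusted over the list alone, adjusted p = 0.000359, and adjusted p = 0.109 with an estimated correlation), with the collagen receptor DDR2 at 3.9 ± 0.07. Of 10 EGF family genes, 8 fell and 1 rose (8 and 1 adjusted over the list alone, adjusted p = 0.00402, and adjusted p = 0.0544 with an estimated correlation), with TGFA at -3.49 ± 0.18. Of 23 cytokines and NF-kB targets, 11 fell and 3 rose (13 and 3 adjusted over the list alone, adjusted p = 0.0172, and adjusted p = 0.208 with an estimated correlation). EMT transcription factors rose in 7 of 13 and fell in 4 (7 and 4 adjusted over the list alone, adjusted p = 0.0227, and adjusted p = 0.124 with an estimated correlation). That list holds SNAI1, the introduced factor, and it was not called without SNAI1 and TWIST1 (11 genes, adjusted p = 0.236), a test chosen after seeing the data. Stem cell and ALDH genes fell in 6 of 13, NRF2 targets in 10 of 19 and unfolded protein response genes in 12 of 20, and 1, 5 and 3 rose (6, 11 and 12 down and 1, 5 and 3 up adjusted over the list alone, adjusted p = 0.0227, 0.0318 and 0.0169). With an estimated correlation these were adjusted p = 0.0656, adjusted p = 0.364 and adjusted p = 0.455. In total 17 of 34 lists were called, 6 up and 11 down, and 8 of these held with an estimated correlation.

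Twist in HMLE was followed by falls of the same adhesion genes in the core set, with CDH1 at -5.65 ± 0.11 and EPCAM at -5.94 ± 0.11. The largest falls were led by KRT5 (-6.73 ± 0.08), ITGB6 (-6.69 ± 0.08), IL1A (-6.5 ± 0.1), MAL2 (-6.36 ± 0.11), the focal adhesion protein TNS4 (-6.08 ± 0.08) and desmoplakin, DSP (-6.08 ± 0.08). The largest rises were led by the fatty acid carrier FABP4 (6.83 ± 0.19, or 114-fold), followed by ENPP2 (6.44 ± 0.09), AK5 (5.9 ± 0.21), the proteoglycan lumican, LUM (5.71 ± 0.08), NID1 (5.62 ± 0.11), the aminopeptidase ANPEP (5.51 ± 0.05) and the second carrier FABP3 (5.41 ± 0.1). ZEB1 rose by 4.03 ± 0.06, VIM by 1.43 ± 0.04 and CDH2 by 1.22 ± 0.07, while FN1 differed by -0.08 ± 0.05 (adjusted p = 0.226). At the 2-fold limit 1453 genes changed, 665 up and 788 down, and by adjusted p alone, the rule of the list counts, 43.72% of all genes.

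With Twist in HMLE the same 5 of 6 epithelial lists fell, and luminal markers were not called (4 fell and 1 rose of 13, 4 and 1 adjusted over the list alone, adjusted p = 0.0886). Epithelial surface and trafficking genes fell in 16 of 16 cases (16 adjusted over the list alone, camera adjusted p = 4.39e-19), and CD24, a surface glycoprotein of luminal cells, fell by 5.47 ± 0.16. Desmosome and hemidesmosome genes fell in 14 of 16 and rose in 1 (14 and 1 adjusted over the list alone, adjusted p = 2.45e-13), with the integrin ITGB4 at -5.49 ± 0.07. All 5 basal keratins fell (5 adjusted over the list alone, adjusted p = 1.31e-06). Junction and polarity genes fell in 15 of 19 and rose in 1 (15 and 1 adjusted over the list alone, adjusted p = 1.35e-10), and epithelial regulators fell in 9 of 14 and rose in 3 (9 and 3 adjusted over the list alone, adjusted p = 0.000918). Mesenchymal markers rose in 16 of 20 and fell in 3 (16 and 3 adjusted over the list alone, adjusted p = 7.76e-07), with THY1 at 2.9 ± 0.1 and ACTG2 at 3.56 ± 0.13. Collagen and matrix genes rose in 19 of 27 and fell in 5 (19 and 5 adjusted over the list alone, adjusted p = 4.99e-08), and fibroblast markers rose in 11 of 15 and fell in 3 (11 and 3 adjusted over the list alone, adjusted p = 1.44e-05). These 8 calls held with an estimated correlation.

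Inflammatory and growth factor genes also moved with Twist in HMLE. Of 23 cytokines and NF-kB targets, 17 fell and 2 rose (18 and 2 adjusted over the list alone, camera adjusted p = 2.52e-07, held with an estimated correlation at adjusted p = 0.0118), with IL1B at -3.68 ± 0.12, the prostaglandin synthase PTGS2 at -3.26 ± 0.1 and CSF3 at -1.92 ± 0.12. Of 10 EGF family genes 7 fell (8 fell and 1 rose adjusted over the list alone, adjusted p = 0.000194, held with an estimated correlation at adjusted p = 0.0118), with TGFA at -3.57 ± 0.18 and HBEGF at -1.79 ± 0.1. TGF-beta pathway genes fell in 13 of 22 and rose in 7 (13 and 7 adjusted over the list alone, adjusted p = 0.0225, and adjusted p = 0.302 with an estimated correlation), led by TGFBI (-4.91 ± 0.06), the activin antagonist FST (-4.47 ± 0.12) and the activin subunit INHBA (-3.71 ± 0.07). The p53 targets rose in 12 of 18 and fell in 3 (12 and 3 adjusted over the list alone, adjusted p = 0.0072, and adjusted p = 0.302 with an estimated correlation). Mesenchymal growth factor receptors and ligands rose in 11 of 19 and fell in 6 (11 and 6 adjusted over the list alone, adjusted p = 0.0458, and adjusted p = 0.302 with an estimated correlation). The cell cycle list was not called (9 of 28 fell, 1 rose; 9 and 1 adjusted over the list alone, adjusted p = 0.16), nor were endothelial (1 rose, 2 fell of 13; 1 and 2 adjusted over the list alone, adjusted p = 0.811) or leukocyte markers (2 rose, 2 fell of 14; 2 and 2 adjusted over the list alone, adjusted p = 0.989). Altogether 13 lists were called, 5 up and 8 down, and 10 held with an estimated correlation.

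Snail in MCF10A changed fewer genes past the 2-fold limit, 329 in all, 132 up and 197 down. The rule of the list counts, adjusted p alone, was met by 22.66% of all genes. CDH1 fell by 0.57 ± 0.11, or 1.48-fold (adjusted p = 0.00112), and EPCAM by 1.65 ± 0.11, while ZEB1 rose by 1.23 ± 0.06, CDH2 by 0.61 ± 0.07 and VIM by 0.44 ± 0.04. FN1 rose by 2.01 ± 0.05. After SNAI1 the largest rises were the stress-responsive ANKRD1 (3.14 ± 0.12), FBN1 (3.07 ± 0.07), the transporter ABCA8 (2.95 ± 0.13), the sulfate-activating enzyme PAPSS2 (2.78 ± 0.07) and the hyaluronan synthase HAS2 (2.75 ± 0.09). The largest falls were the secretoglobin SCGB1A1 (-4.35 ± 0.1), the kallikrein KLK7 (-3.75 ± 0.09), the secreted glycoprotein AZGP1 (-3.72 ± 0.14), the keratin KRT15 (-3.48 ± 0.12), BBOX1 (-3.27 ± 0.09), and the death ligand TNFSF10 (-3.15 ± 0.12).

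Epithelial and matrix lists moved in MCF10A with Snail as well. Of 19 junction and polarity genes 15 fell (17 adjusted over the list alone, camera adjusted p = 3.65e-11), of 16 surface and trafficking genes 14 fell (14 adjusted over the list alone, adjusted p = 3.65e-11), and of 14 epithelial regulators 9 fell (9 adjusted over the list alone, adjusted p = 3.03e-07), led by ELF3 (-2.85 ± 0.11) and GRHL1 (-1.29 ± 0.12). Of 27 collagen and matrix genes 18 rose (20 adjusted over the list alone, adjusted p = 2.18e-18), with FBLN5 at 2.06 ± 0.08 and MFAP5 at 1.92 ± 0.07. Of 20 mesenchymal markers 12 rose (13 adjusted over the list alone, adjusted p = 1.74e-10), and of 15 fibroblast markers 7 rose (8 adjusted over the list alone, adjusted p = 2.44e-05), including FAP (1.68 ± 0.1). Interferon response genes fell in 10 of 26 and rose in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.00168), with OAS1 at -1.54 ± 0.08 and IFITM1 at -1.5 ± 0.09. These 7 calls held with an estimated correlation. Basal keratins fell in 3 of 5 cases (3 adjusted over the list alone, adjusted p = 0.0329, and adjusted p = 0.157 with an estimated correlation), and KRT5 differed by 0.05 ± 0.08 (adjusted p = 0.733). Luminal markers were not called (4 fell of 13, 4 adjusted over the list alone, adjusted p = 0.181). Desmosome and hemidesmosome genes fell in 9 of 16 and rose in 4 (9 and 4 adjusted over the list alone, adjusted p = 0.0257, and adjusted p = 0.0768 with an estimated correlation).

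Other lists were called in MCF10A with Snail under the preset correlation. Of 23 cytokines and NF-kB targets 11 rose and 2 fell (12 and 3 adjusted over the list alone, adjusted p = 0.000267, and adjusted p = 0.0768 with an estimated correlation), with ICAM1 at 1.81 ± 0.06 and CXCL1 at 0.96 ± 0.11. Of 22 TGF-beta pathway genes 10 rose and 4 fell (11 and 4 adjusted over the list alone, adjusted p = 3.32e-05, and adjusted p = 0.0847 with an estimated correlation), with CCN2 at 1.97 ± 0.05 and TGFB2 at 1.41 ± 0.06. Of 17 cholesterol synthesis genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 7.9e-06, and adjusted p = 0.0582 with an estimated correlation), with LSS at 0.59 ± 0.06. Of 28 cell cycle genes 12 rose (13 adjusted over the list alone, adjusted p = 4.68e-07, and adjusted p = 0.247 with an estimated correlation). Of 26 respiratory chain genes 13 fell (19 adjusted over the list alone, adjusted p = 1.28e-06, and adjusted p = 0.0847 with an estimated correlation). Of 24 glycolysis genes 11 fell and 1 rose (11 and 1 adjusted over the list alone, adjusted p = 0.00149, and adjusted p = 0.173 with an estimated correlation). Endothelial markers (1 fell of 13; 1 adjusted over the list alone, adjusted p = 0.84) and leukocyte markers (2 rose, 2 fell of 14; 2 and 2 adjusted over the list alone, adjusted p = 0.836) were not called. In total 15 lists were called, 7 up and 8 down, of which 7 held with an estimated correlation.

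**Figure D2:**
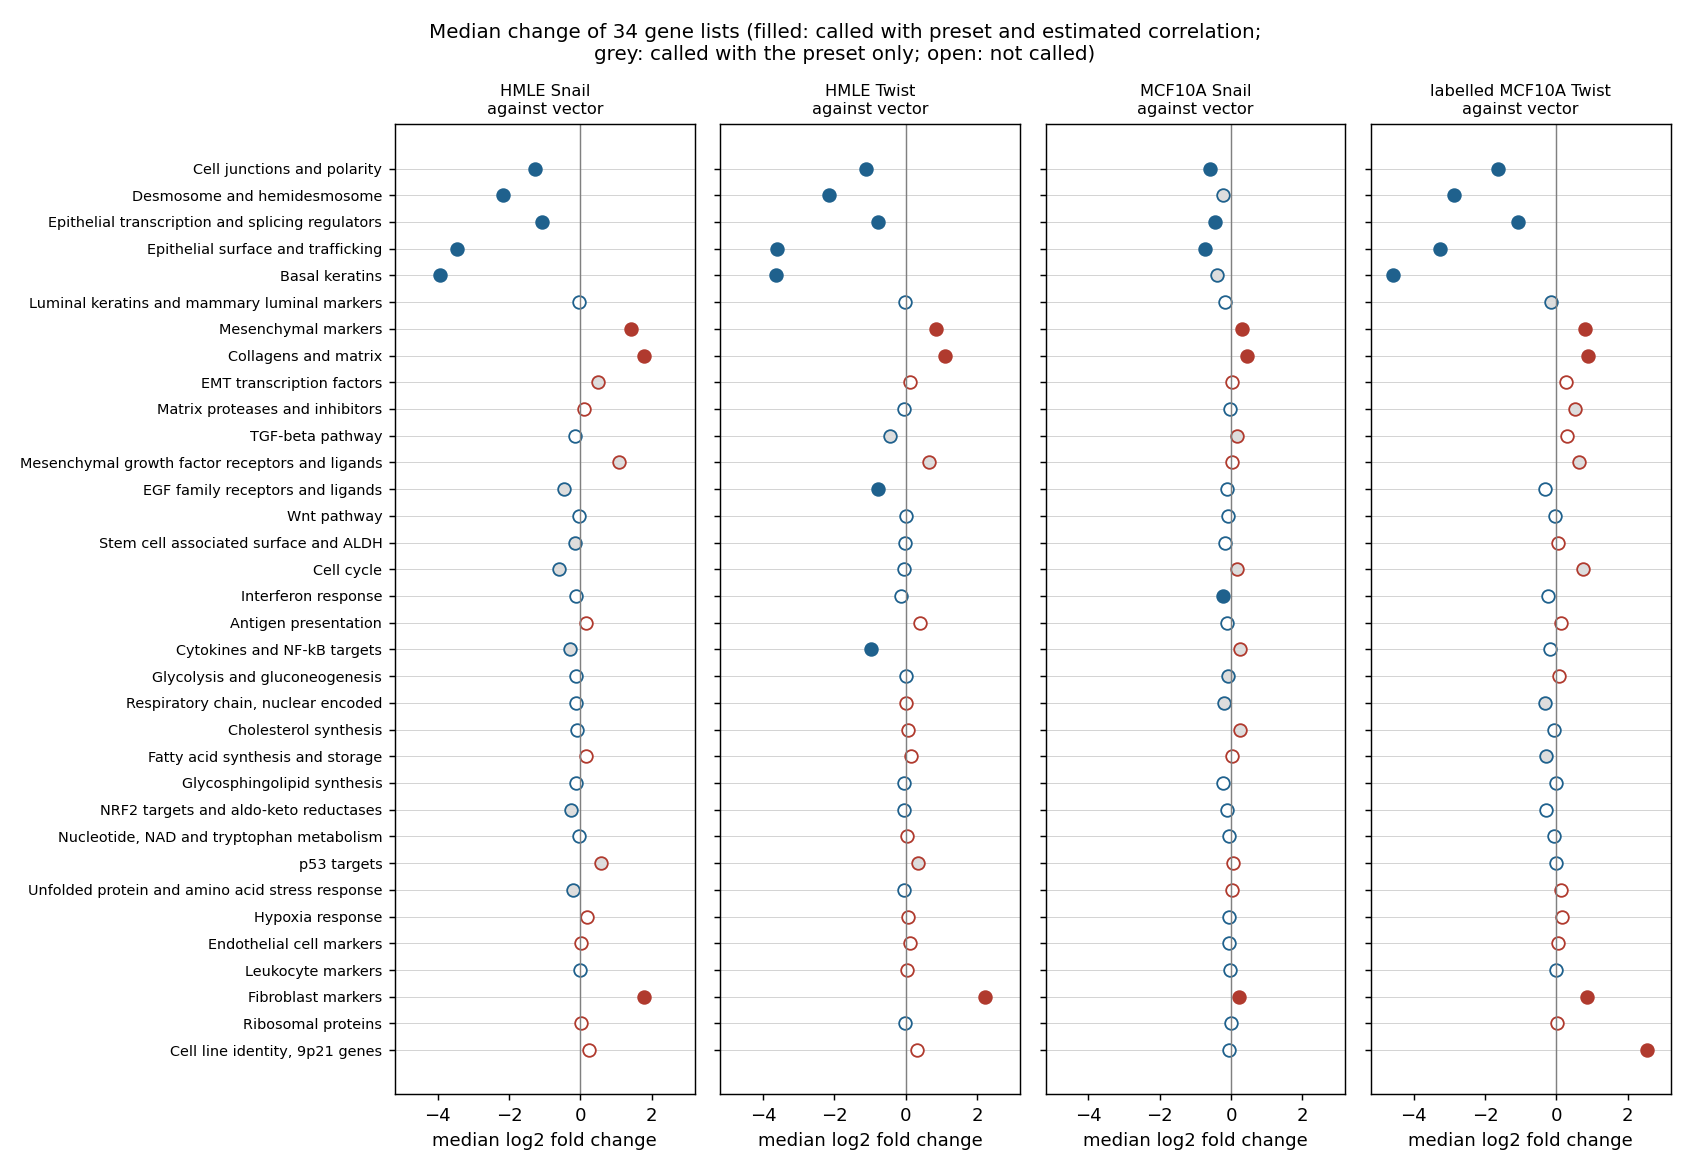
Median log2 fold change of 34 gene lists in the 4 comparisons with vector, one row per list; red is above 0 and blue below, filled circles were called with the preset and the estimated correlation, grey circles with the preset only, and open circles not. Basal keratins lie at a median of -3.95 in HMLE Snail and -0.4 in MCF10A Snail.

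The arrays labelled MCF10A Twist differed from MCF10A vector at 1937 genes, 956 higher and 981 lower at the 2-fold limit, and the line identity genes given above moved with this comparison. Adjusted p alone, the rule of the list counts, was met by 50.4% of all genes. CDH1 was lower by -5.42 ± 0.11 on the log2 scale and EPCAM by -5.51 ± 0.11, while ZEB1 was higher by 3.73 ± 0.06, CDH2 by 2.4 ± 0.07, FN1 by 2.01 ± 0.05 and VIM by 0.89 ± 0.04. The largest positive differences were the urea transporter SLC14A1 (7.28 ± 0.16), NID1 (6.5 ± 0.11), ENPP2 (6.24 ± 0.09), the matrix protein EDIL3 (6.05 ± 0.18), SLFN11 (5.88 ± 0.1) and THY1 (5.31 ± 0.1). The largest negative differences were MAL2 (-7.82 ± 0.11), the calcium-binding S100A8 (-7.13 ± 0.12), the calcium sensor VSNL1 (-6.58 ± 0.13), DSC3 (-6.55 ± 0.13), SLPI (-6.53 ± 0.09), KRT5 (-6.38 ± 0.08) and the cytokine IL18 (-6.34 ± 0.1). Set against the HMLE vector arrays, an alternative chosen after seeing the data, the FN1 difference turned to -0.36.

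List directions in the arrays labelled MCF10A Twist, subject to the same limit, were as follows. Surface and trafficking genes were lower in 16 of 16 (16 adjusted over the list alone, camera adjusted p = 1e-14), desmosome and hemidesmosome genes lower in 15 of 16 and higher in 1 (15 and 1 adjusted over the list alone, adjusted p = 5.36e-12), junction and polarity genes lower in 16 of 19 (17 adjusted over the list alone, adjusted p = 1.39e-10), epithelial regulators lower in 11 of 14 (11 adjusted over the list alone, adjusted p = 9.76e-07) and basal keratins lower in 5 of 5 (5 adjusted over the list alone, adjusted p = 2.54e-06). Mesenchymal markers were higher in 16 of 20 and lower in 3 (16 and 3 adjusted over the list alone, adjusted p = 8.56e-07), collagen and matrix genes higher in 20 of 27 and lower in 3 (21 and 3 adjusted over the list alone, adjusted p = 3.94e-07), and fibroblast markers higher in 11 of 15 and lower in 1 (12 and 1 adjusted over the list alone, adjusted p = 1.51e-05). These 8 calls held with an estimated correlation. Cell cycle genes were higher in 27 of 28 and lower in 1 (27 and 1 adjusted over the list alone, adjusted p = 1.39e-10, and adjusted p = 0.18 with an estimated correlation), with E2F1 at 1.22 ± 0.07 and MCM2 at 1.18 ± 0.08. Against HMLE vector, the alternative chosen after seeing the data, the cell cycle (adjusted p = 0.104), luminal (0.156), matrix protease (0.19), mesenchymal growth factor (0.0601), fatty acid (0.0982) and 9p21 (0.0925) lists were not called. Respiratory chain genes were lower in 22 of 26 and higher in 1 (23 and 2 adjusted over the list alone, adjusted p = 5e-05, and adjusted p = 0.18 with an estimated correlation). Both lists also differed in the same direction between HMLE and MCF10A vector arrays, as given below. Luminal markers were lower in 5 of 13 and higher in 1, fatty acid genes lower in 8 of 13 and higher in 1, matrix proteases higher in 12 of 20 and lower in 4, and mesenchymal growth factor genes higher in 10 of 19 and lower in 4. Adjusted over the list alone these were 5 and 1, 8 and 1, 13 and 4, and 10 and 4, with adjusted p = 0.0267, 0.0135, 0.00394 and 0.0326. With an estimated correlation they were adjusted p = 0.219, adjusted p = 0.18, adjusted p = 0.219 and adjusted p = 0.298. Endothelial (2 lower of 13; 2 adjusted over the list alone, adjusted p = 0.758) and leukocyte markers (2 higher and 3 lower of 14; 1 and 3 adjusted over the list alone, adjusted p = 0.462) were not called. In all 15 lists were called, 7 up and 8 down, and 9 held with an estimated correlation.

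**Figure D3:**
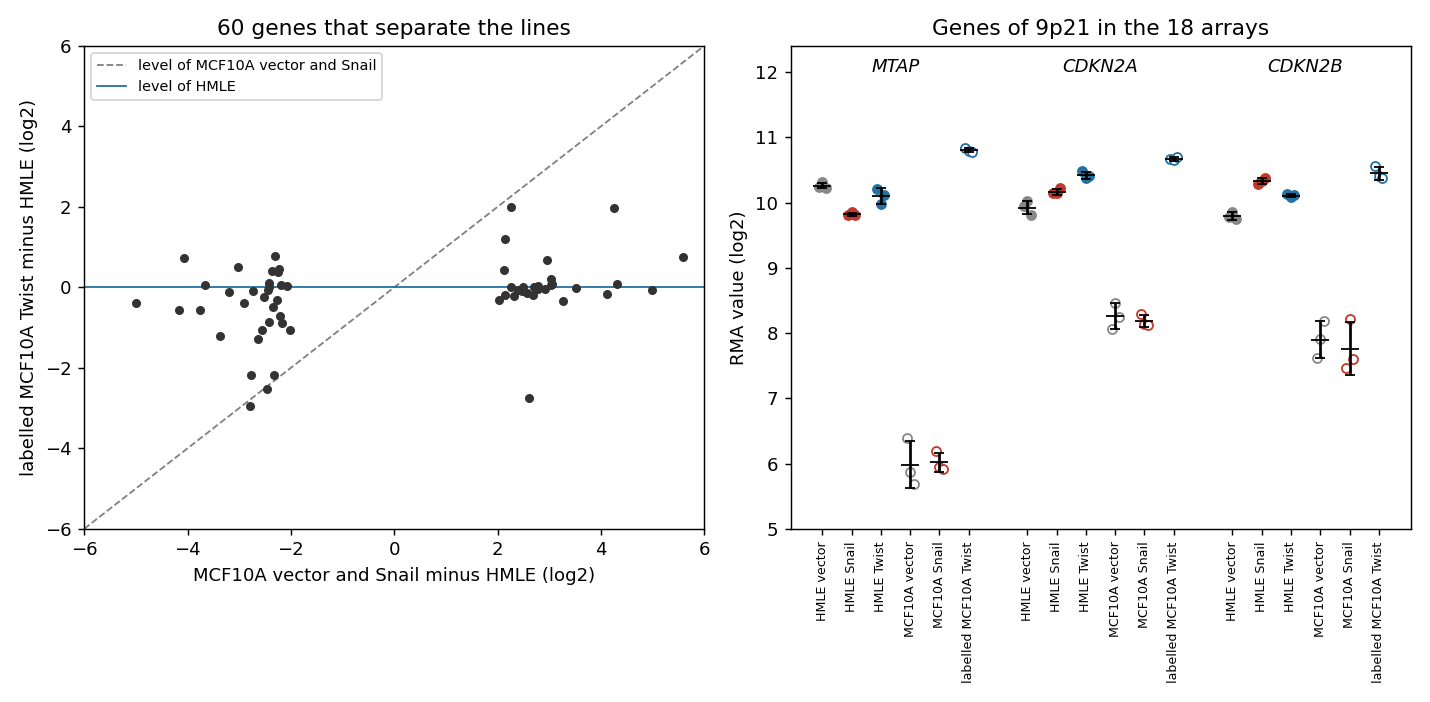
Left, 60 genes that separated the lines without use of the arrays labelled MCF10A Twist, with the log2 difference of MCF10A vector and Snail arrays from HMLE on the x axis and that of the labelled arrays on the y axis; right, RMA values (log2) of the 9p21 genes per array with mean and SD. On the left 46 of 60 points lie at least 0.75 of the way to the HMLE level (horizontal line).

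Snail and Twist were compared directly within each line. In HMLE 519 genes differed, 332 higher and 187 lower with Snail. Besides SNAI1 (5.01 ± 0.09), the heparan sulfatase SULF1 (4.58 ± 0.09), the adhesion molecule NRCAM (4.36 ± 0.08) and GPM6B (4.32 ± 0.15) were higher with Snail. FABP4 (-5.37 ± 0.19), the ubiquitin ligase RNF182 (-4.35 ± 0.08) and LUM (-3.91 ± 0.08) were lower with Snail. CDH1 differed by 0.01 ± 0.11 (adjusted p = 0.975), VIM by 0.01 ± 0.04 (adjusted p = 0.893) and ZEB1 by -0.18 ± 0.06 (adjusted p = 0.03). In MCF10A 1599 genes differed between the Snail arrays and the arrays labelled MCF10A Twist, 818 higher and 781 lower with Snail, with the same limit on line identity. MAL2 (7.67 ± 0.11), IL18 (6.56 ± 0.1) and KRT5 (6.43 ± 0.08) were higher with Snail, and SLC14A1 (-7.21 ± 0.16), NID1 (-6.34 ± 0.11) and EDIL3 (-6.16 ± 0.18) were lower. Of 34 lists 12 were called in HMLE, 9 up and 3 down with Snail, and 0 held with an estimated correlation. In MCF10A 16 were called, 9 up and 7 down, and 6 held.

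The fold changes of the factors were correlated across genes in HMLE with r = 0.847, genes not being independent replicates. Both used the same 3 vector arrays, and simulated groups without any effect gave r = 0.499. The covariance was 0.432, against 0.00506 in the simulation. In HMLE 465 genes rose and 599 fell with both factors, where independent lists would share 29.68 and 34.79. In MCF10A, with the arrays as labelled, r was 0.456 against 0.498 in the simulation, and the covariance 0.113 against 0.00504. There 66 genes rose and 157 fell in both, where independent lists would share 6.852 and 10.49. With the arrays labelled MCF10A Twist set against HMLE vector, an alternative chosen after seeing the data, this r was lower, as given with the alternatives. The fold changes then share no vector arrays, so the simulated 0.498 does not apply to that r. The simulated covariance holds the spread between arrays of the shared controls, and the covariances exceeded it by 0.427 in HMLE and 0.108 in MCF10A. An offset of the vector cells themselves enters both fold changes and was not simulated, so these differences do not isolate a shared effect. In MCF10A the difference may also hold the line identity of the arrays labelled MCF10A Twist. For the shared genes, 3 vector arrays cannot be split into parts of at least 2 each, so part of the excess over independent lists may come from the shared controls.

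**Figure D4:**
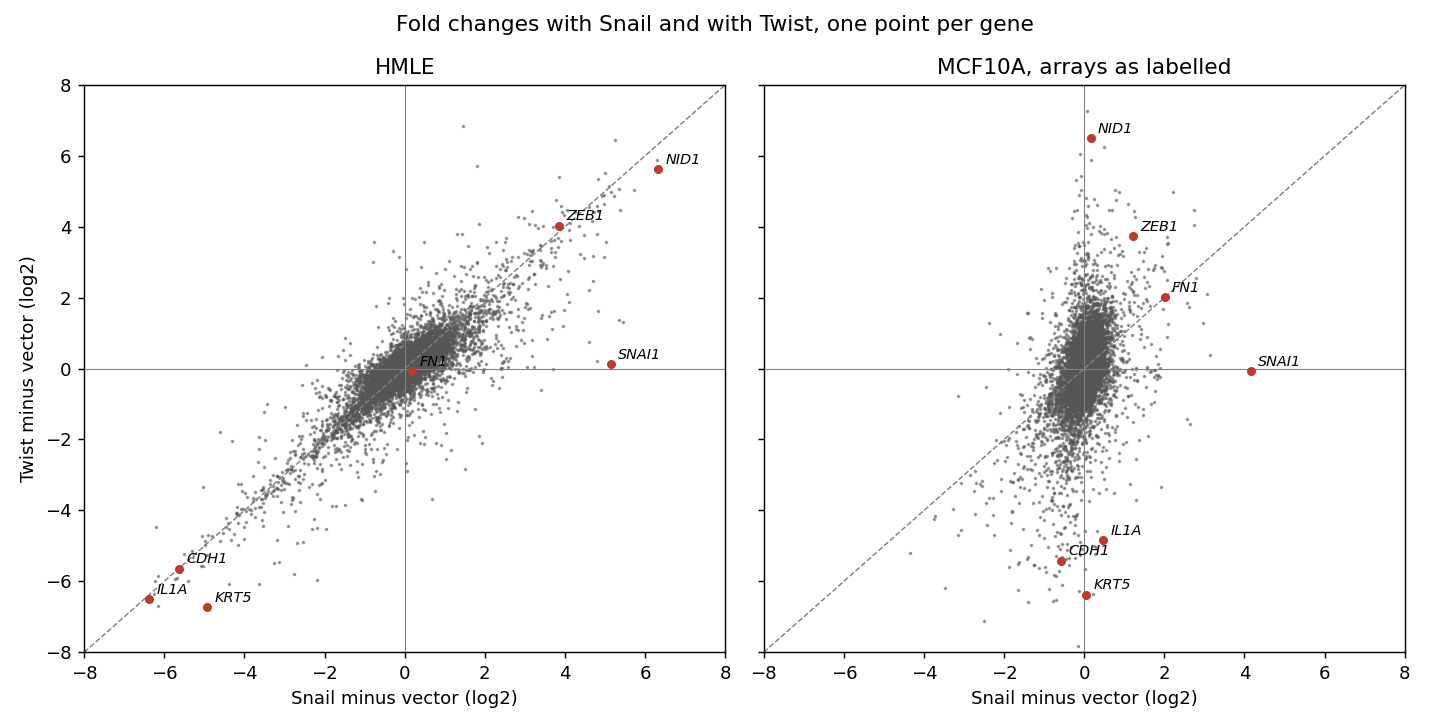
Log2 fold change with Snail (x axis) against that with Twist (y axis), one point per gene, in HMLE (left, r = 0.847) and MCF10A with arrays as labelled (right, r = 0.456); the dashed line marks equal change. SNAI1 lies at 5.14 on the x axis and 0.13 on the y axis in HMLE.

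The lines were compared through the difference of their fold changes. Snail changed 174 genes the same way in both lines, 81 up and 93 down, where independent lists would share 5.892 and 8.696. The Snail effect differed between lines at 1587 genes, 843 with the higher change in HMLE and 744 in MCF10A. By adjusted p alone, as in the list counts, it differed at 40.15% of all genes. The change was lower in HMLE for CDH1 (-5.07 ± 0.16), EPCAM (-4.07 ± 0.15), IL1A (-6.85 ± 0.14) and MFAP5 (-7.2 ± 0.1), and higher in HMLE for NID1 (6.17 ± 0.15), LIN7A (5.57 ± 0.14) and ZEB1 (2.62 ± 0.08). The difference of the Snail effect between lines was called for 14 lists, 7 of them with an estimated correlation too, among them surface and trafficking genes (16 of 16 lower in HMLE, 16 adjusted over the list alone, camera adjusted p = 9.38e-16). It was not called for epithelial regulators (7 lower and 4 higher of 14, 8 and 4 adjusted over the list alone, adjusted p = 0.126) or luminal markers (3 lower and 1 higher of 13, 3 and 1 adjusted over the list alone, adjusted p = 0.478). For FN1 the difference was -1.82 ± 0.07, but FN1 stood at 14.3 in HMLE and 11.93 in MCF10A vector arrays, so it may reflect starting levels. The highest value of any probe set in HMLE vector arrays was 14.79 to 14.88, so a large rise in HMLE may not have registered. FN1 did reach 14.48 with Snail in HMLE, and saturation was not tested. By line identity as labelled, Twist changed 773 genes the same way in both lines, 328 up and 445 down, where independent lists would share 34.52 and 41.97. The Twist effect differed at 1509 genes, 767 with the higher change in HMLE and 742 in MCF10A as labelled. That count was 627 when the arrays labelled MCF10A Twist were set against HMLE vector, an alternative chosen after seeing the data. The vector arrays cancel there, so 627 counts genes that differed between HMLE Twist arrays and the arrays labelled MCF10A Twist. With arrays as labelled, the difference of the Twist effect was called for 10 lists, 5 up and 5 down in HMLE, and 0 held with an estimated correlation. FABP4 (6.23 ± 0.27) and ANPEP (6.18 ± 0.07) had the higher change in HMLE, while TFPI2 (-7.13 ± 0.19) and UCA1 (-5.66 ± 0.14) had the lower. ANPEP, TFPI2 and UCA1 already differed between the vector arrays in the opposite direction, as given below, so their differences may reflect starting levels.

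Across all 4 comparisons with vector, 121 genes changed the same way, 44 up and 77 down. Independent lists would share 0.01104 and 0.01982, a value that leaves out the shared vector arrays. By the smallest of their 4 changes the leading rises were PTX3, FBN1, ENPP1, HAS2 and PAPSS2, and the leading falls were KRT15, ST6GALNAC2, KLK10, S100A8 and SPRR2A. HAS2, for instance, rose by 3.93 ± 0.09 and 4.43 ± 0.09 with Snail and Twist in HMLE and by 2.75 ± 0.09 with Snail in MCF10A, and was higher by 4.04 ± 0.09 in the arrays labelled MCF10A Twist. The sialyltransferase ST6GALNAC2 changed by -3.05 ± 0.09, -4.04 ± 0.09, -2.43 ± 0.09 and -4.41 ± 0.09 in the same order.

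The vector arrays of the lines differed at 1170 genes, 612 higher in HMLE and 558 higher in MCF10A. By adjusted p alone, as in the list counts, they differed at 43.99% of all genes. UCA1, a long noncoding RNA (5.83 ± 0.1), the adhesion molecule CNTN1 (4.88 ± 0.08), TFPI2 (4.69 ± 0.13) and INHBA (4.68 ± 0.07) were higher in HMLE. The aminopeptidase ANPEP (-5.85 ± 0.05), the kynureninase KYNU (-5.48 ± 0.07) and SCGB1A1 (-5.41 ± 0.1) were higher in MCF10A. FN1 was higher in HMLE by 2.37 ± 0.05, a difference that may be understated, since FN1 lay near the highest values of the HMLE vector arrays. CDH1 differed by 0 ± 0.11. MTAP and the other 9p21 list genes were all higher in HMLE (3 of 3; 3 adjusted over the list alone, camera adjusted p = 0.000993, and adjusted p = 0.0771 with an estimated correlation). Cell cycle genes were higher in HMLE in 26 of 28 and lower in 1 (27 and 1 adjusted over the list alone, adjusted p = 2.39e-10, and adjusted p = 0.298 with an estimated correlation). Respiratory chain genes were lower in HMLE in 24 of 26 (25 adjusted over the list alone, adjusted p = 2.43e-10, and adjusted p = 0.0771 with an estimated correlation). Cholesterol synthesis genes were higher in 14 of 17 and lower in 2 (14 and 2 adjusted over the list alone, adjusted p = 1.62e-05, and adjusted p = 0.11 with an estimated correlation), and unfolded protein response genes higher in 14 of 20 and lower in 2 (15 and 2 adjusted over the list alone, adjusted p = 0.000212, and adjusted p = 0.301 with an estimated correlation). Mesenchymal markers were higher in 12 of 20 and lower in 4 (14 and 4 adjusted over the list alone, adjusted p = 0.0039, and adjusted p = 0.133 with an estimated correlation), collagen and matrix genes higher in 15 of 27 and lower in 7 (15 and 7 adjusted over the list alone, adjusted p = 0.0435, and adjusted p = 0.298 with an estimated correlation). Epithelial regulators were lower in 8 of 14 and higher in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.0103, and adjusted p = 0.0771 with an estimated correlation). The p53 targets were lower in 11 of 18 and higher in 5 (11 and 6 adjusted over the list alone, adjusted p = 0.029, and adjusted p = 0.542 with an estimated correlation), and ribosomal proteins lower in 14 of 23 and higher in 1 (15 and 1 adjusted over the list alone, adjusted p = 0.0169, and adjusted p = 0.298 with an estimated correlation). These 10 lists were called, 6 up and 4 down in HMLE, and 0 held with an estimated correlation.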

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

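The tests of cell identity and of the weaker Snail response were chosen only after the results they address were seen. The splits of the samples and the differences between lines were planned. The gap test for single distant arrays needs 4 arrays in a group and was not made. Arrays did differ in their spread, with weights estimated over all 18 arrays from 0.182 (HMLE Twist replicate 1) to 77.3 (HMLE Twist replicate 3), an estimate that stopped short of its tolerance.

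The fold changes with Snail differed between the lines at 1587 genes by a test of their difference. The change was more positive in HMLE for NID1 (6.17), the enteropeptidase TMPRSS15 (5.67), the polarity scaffold LIN7A (5.57), AK5 (5.41), the small nucleolar RNA SNORD114-3 (5.23), ZEB1 (2.62), VIM (1), SNAI1 (0.98), TWIST1 (0.88) and CDH2 (0.56). It was more negative in HMLE for MFAP5 (-7.2), IL1A (-6.85), UCA1 (-6.14), MAL2 (-6.11), ITGB6 (-5.78), CDH1 (-5.07), EPCAM (-4.07) and FN1 (-1.82). UCA1 and FN1 (14.3 against 11.93) were already higher in HMLE than in MCF10A vector arrays, and SNAI1 (7.39 against 8.32) was lower. With Snail, SNAI1 stood at 12.53 in HMLE and 12.49 in MCF10A, and FN1 at 14.48 and 13.94. The differences of UCA1, FN1 and SNAI1 may therefore reflect starting levels. FN1 stood at 14.3 in HMLE vector arrays, where the highest value of any probe set was 14.79 to 14.88. A large rise there may not have registered, though FN1 reached 14.48 with Snail and saturation was not tested. Of 100 splits of the arrays within each line, 4 called as many genes, the real one included, and the highest other called 1756. The 3 others kept the HMLE arrays as labelled, so the HMLE effect alone gives such counts and the splits do not test a difference between the lines. With neither line as labelled the highest count was 0. For the 174 genes that Snail changed the same way in both lines, 1 of 100 splits gave as many and the highest other gave 0. Splits that mix the groups of a line called 0 genes in that line, so a shared count of 0 there was given in advance.

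The fold changes with Twist, with arrays as labelled, differed between the lines at 1509 genes by the same test. The change was more positive in HMLE for RANBP17 (6.38), FABP4 (6.23), ANPEP (6.18), TMPRSS15 (5.41), the cadherin CDH10 (5.33), TWIST1 (0.88), VIM (0.53) and ZEB1 (0.3). It was more negative in HMLE for the protease inhibitor TFPI2 (-7.13), UCA1 (-5.66), SLC14A1 (-5.49), FST (-5.4), TGFBI (-5.04), FN1 (-2.1), CDH2 (-1.18) and EPCAM (-0.44). The limits on FN1 given above, its unequal starting levels and its 14.3 in HMLE vector arrays, hold here too. ANPEP, TFPI2 and UCA1 already differed between the vector arrays in the opposite direction, so their differences may reflect starting levels. Of 100 splits 4 called as many genes, the real one included, and the highest other called 2150. The 3 others kept the MCF10A arrays as labelled, so these arrays alone give such counts, the splits do not test a difference between the lines, and with neither line as labelled the highest count was 0. For the 773 genes shared by the lines, 1 of 100 splits gave as many and the highest other gave 0, again a count given in advance.

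The first pattern weighed is the 9p21 genes at HMLE levels in the 3 arrays labelled MCF10A Twist. MTAP stood at 10.8 there, against 5.98 and 6.02 in MCF10A vector and Snail arrays, CDKN2A at 10.67 against 8.26 and 8.18, and CDKN2B at 10.45 against 7.9 and 7.76. A change of these genes by Twist within MCF10A cells would leave the line differences over runs of neighbouring genes in place. Over 190 runs of 50 genes, the line difference of the vector arrays correlated with that of the Snail arrays at 0.602 (0.446 to 0.721) and with that of the Twist arrays at 0.152 (0.0054 to 0.303). This argues against such a change, with a limit. MCF10A Snail arrays differed from vector at 329 genes and the arrays labelled MCF10A Twist at 1937. Part of the lower correlation may thus come from a larger change of expression, and its interval still lies above 0. An admixture of HMLE cells to MCF10A cells that kept the transcripts high in MCF10A would keep part of these transcripts. The median share kept was -0.000236 (-0.0088 to 0.00414), which argues against such an admixture. These genes were stable between MCF10A vector and Snail arrays, but their response to Twist in MCF10A cells is not known. MCF10A cells that lost these transcripts with Twist would give the same share, so an admixture with such cells stays open. Cells other than the MCF10A of the vector and Snail arrays remain a candidate explanation: over 60 genes that separated the lines without these arrays, the median position was 0.982 (0.91 to 1.01), with 0 for MCF10A and 1 for HMLE. Of these genes 46 lay at 0.75 or above and 5 below 0.25, NAV3, NMRAL2P, SECTM1, ZNF518B and ZNF542P, which were named after their values were seen. The 60 genes include MTAP (1.18) and CDKN2B (1.16), which belong to the pattern to be explained and so add no support of their own. Whether Twist moves the other genes in MCF10A cells was not tested, which limits the median position too. Which cells these were stays open, as does whether a label or a culture was exchanged.

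The second pattern weighed is the smaller number of genes changed by Snail in MCF10A, 329 against 1635 in HMLE. By adjusted p alone the counts were 4173 against 8786, so the size of the gap depends on the 2-fold limit. Of 231 genes that Snail changed at least 8-fold in HMLE, 139 changed in the same direction in MCF10A, 57 of them at least 2-fold, and 11 went the opposite way. Their median absolute log2 change in HMLE was 3.74, and their median log2 change in MCF10A, counted in the direction of HMLE, was 0.44. Choosing genes by a large change in HMLE favours HMLE. Of the 329 genes chosen by their change in MCF10A, 225 changed in the same direction in HMLE, 174 of them at least 2-fold, and 46 went the opposite way. For these the median absolute log2 change was 1.41 in MCF10A, and the median in HMLE, counted in the direction of MCF10A, was 1.11. Less SNAI1 transcript in MCF10A is argued against by a difference of -0.04 (SE 0.09) between the Snail arrays of the lines, although protein was not measured. A minority of fully changed cells could lower no gene by more than it lowered CDH1, yet 206 genes fell by more than CDH1 with intervals apart, which argues against that explanation. The normalization of the deposited values stays open. The ratio of the counts was 0.201 as reported and at most 0.204 after quantile normalization or median centring, but these values had been normalized before and a second normalization hardly moved the counts, so it decides nothing. A difference between the lines in their response to Snail may explain the pattern, as a hypothesis, and the choice of clones, for which the labels give no replicate, stays open and was not tested.

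Probe sets without a single gene name, which the comparisons of genes leave out, also changed. Of 13837 such probe sets, 281 changed with Snail and 213 with Twist in HMLE, 112 with Snail in MCF10A, and 423 differed in the arrays labelled MCF10A Twist. These counts were not explored further.

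In the comparisons of 3 arrays with 3, there are 10 splits, too few for a share under 0.05. The real split was the 1 of 10 that called as many genes in each of the 7 comparisons of pairs of groups: 1635, 1453, 329 and 1937 genes against vector, 519 and 1599 for Snail against Twist in HMLE and MCF10A, and 1170 between vector lines, where the highest other split called 0. The other splits mix groups that differ, which widens the spread within groups, so their count of 0 says little about chance. The real split was also the 1 of 10 for lists against vector, with 17 lists for HMLE Snail (highest other 13), 13 for HMLE Twist (11), 15 for MCF10A Snail (12) and 15 for the arrays labelled MCF10A Twist (13). Mixed splits came near these counts, so the splits give the list counts no support. For the 121 genes changed the same way in all 4 comparisons, 1 of 100 random splits gave as many and the highest other gave 0, which says little, since a gene has to be called in 4 comparisons of mixed groups. For the correlation of Snail and Twist effects, 38 of 100 random splits gave r as high as 0.847 in HMLE (highest other 0.968). In MCF10A 61 of 100 gave r as high as 0.456 (highest other 0.986). By r alone chance is not excluded, but the splits cannot decide this, since they mix vector, Snail and Twist arrays. Real differences between groups thus enter r, beside the shared control, which alone gave 0.499 and 0.498 in simulations with no effect. The covariance, of 0.432 in HMLE and 0.113 in MCF10A, lay above the 0.00506 and 0.00504 of those simulations, which share the controls too. The differences, 0.427 and 0.108 (in MCF10A with arrays as labelled), do not isolate a shared effect, since an offset of the vector cells was not simulated.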

How the results depend on the processing

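The 2 alternatives on the arrays labelled MCF10A Twist and the lists without SNAI1 and TWIST1 were chosen after seeing the data, and the others were planned. With 1 array left out at a time, counts against vector ranged over 1632 to 1662 (HMLE Snail), 1431 to 1491 (HMLE Twist), 324 to 353 (MCF10A Snail) and 1881 to 1974 (arrays labelled MCF10A Twist). Other counts ranged over 512 to 547 and 1560 to 1625 (Snail against Twist), 1569 to 1637 and 1497 to 1538 (differences of Snail and Twist effects), 1160 to 1190 (vector lines), 170 to 184 and 759 to 789 (shared between lines) and 119 to 128 (all 4). The correlations ranged over 0.843 to 0.848 in HMLE and 0.439 to 0.467 in MCF10A, and lists called over 17 to 17, 12 to 16, 15 to 18 and 15 to 15.

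Without the 2-fold limit the adjusted p alone gave 8786, 8052, 4173 and 9282 genes against vector in that order, 5921 and 9119 for Snail against Twist, 7395 and 7185 for the differences of effects and 8102 for vector lines. A test against 0.5 on the log2 scale, which asks for less than the 2-fold limit, gave 2590, 2154, 448 and 3101 genes against vector in the same order. It gave 849 and 2660 (Snail against Twist), 2096 and 2060 (differences of effects) and 1931 (vector lines). Array weights, whose estimate stopped short of its tolerance and gave 1 HMLE Twist array a weight of 77.3, moved the HMLE correlation to 0.843 and the CDH1 difference of HMLE Snail and Twist from 0.01 to -0.15, where it passed the test. Leaving out dim genes, which kept 10551 and removed GRHL1 (MCF10A Snail against vector), moved the correlations to 0.859 and 0.473. Lists called went from 17 to 13 for HMLE Snail (EMT factors, stem cell genes, cytokines and NRF2 targets lost), from 13 to 11 for HMLE Twist (TGF-beta and mesenchymal growth factor genes), from 15 to 13 for MCF10A Snail (desmosome genes and basal keratins) and from 15 to 13 for the arrays labelled MCF10A Twist (mesenchymal growth factor and fatty acid genes). The cause of these shifts was not tested.

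An estimated correlation left 8 lists called for HMLE Snail, 7 for MCF10A Snail and 9 for the arrays labelled MCF10A Twist. With fry, which does not compare a list with other genes, 31, 28, 28 and 31 lists were called. Among the pairs of groups checked, the pairing check gave reason for a block by replicate number only between MCF10A Snail and the arrays labelled MCF10A Twist. With this block that comparison held 1599 genes. Lists called went from 13 to 12 for HMLE Twist and from 15 to 14 for the arrays labelled MCF10A Twist, mesenchymal growth factor genes losing their call in both (adjusted p = 0.066 and 0.0529). With the block set within each line the same list lost its call in both, and basal keratins in MCF10A Snail, which went from 15 to 14. Basal keratins there also lost their call without MCF10A vector replicate 3 (adjusted p = 0.0624). That list of growth factor genes in HMLE Twist also lost its call with array weights, quantile normalization, the mean of probe sets, the arrays labelled MCF10A Twist left out, and HMLE Twist replicate 1 or replicate 2 of the arrays labelled MCF10A Twist left out. In the arrays labelled MCF10A Twist it also lost its call with array weights and with only the groups of the comparison in the fit. The latter also lost EMT factors and NRF2 targets in HMLE Snail (both adjusted p = 0.0538) and basal keratins in MCF10A Snail (0.0576). Quantile normalization lost desmosome genes in MCF10A Snail (0.0588), and array weights lost TGF-beta genes in HMLE Twist (0.0521) and luminal markers in the arrays labelled MCF10A Twist (0.0529). Calls were gained in HMLE Twist and MCF10A Snail with trended and robust variance, array weights or another normalization, among EMT factors, NRF2 targets, fatty acid and mesenchymal growth factor genes. Without SNAI1 and TWIST1, 16 lists were called for HMLE Snail, EMT transcription factors losing their call.

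Set against HMLE vector, the arrays labelled MCF10A Twist had FN1 at -0.36, SNAI1 at 0.86, INHBA at -3.4 and KYNU at 0.6, each with the opposite sign, the Twist effect differed at 627 genes, and the MCF10A correlation was 0.193, through the change of control. The fold changes behind this correlation share no vector arrays. The cell cycle, luminal, protease, growth factor, fatty acid and 9p21 lists lost their call, and EGF family (adjusted p = 0.000475), cholesterol (0.000147), ribosomal (0.0106), cytokine (0.0373), NRF2 (0.0367) and unfolded protein (0.0367) lists gained one. Of 5075 values of the named genes under alternatives, 5 turned to the opposite sign with a call before or after. A turn of sign between values that were not called was not counted. With the sign kept, 29 lost their call and 10 gained one. Dim genes near background limit the changes that the arrays resolve.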

Other observations

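The values in this part were chosen after they were seen, and no test was planned for them. MEG3, an imprinted noncoding RNA, stood at 7.87 in HMLE vector arrays, 11.39 with Snail and 10.69 with Twist, and at 7.4, 7.33 and 7.94 in MCF10A vector, Snail and labelled Twist arrays. MEG3 and the measured SNORD113 and SNORD114 genes of its locus were picked by name, and other genes of the locus were not looked at. Of these 7 genes (MEG3, SNORD113-3, SNORD113-4, SNORD114-2, SNORD114-26, SNORD114-3 and SNORD114-6), 7 were higher with Snail and 7 with Twist in HMLE, with median log2 changes of 3.46 and 2.93. In MCF10A 0 were higher and 1 lower with Snail, and 4 were higher in the arrays labelled MCF10A Twist, with medians of -0.07 and 0.53.

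The spread within groups had 1 main axis, holding 41.23% of the residual variance against 8.106% for the next. Its scores for replicates 1 and 2 were 2.22 and -2.01 in HMLE Twist, 1.61 and -1.08 in the arrays labelled MCF10A Twist, 1.15 and -0.96 in MCF10A Snail, 0.63 and -0.16 in MCF10A vector, and 0.21 and -0.39 in HMLE Snail arrays. In HMLE vector arrays they had the opposite signs, -0.42 and 1.1. Replicate 1 scored above replicate 2 in 5 of 6 groups. Replicate 3 scored -0.21, -0.53, -0.18, -0.47 and 0.18 in the first 5 of these groups and -0.68 in HMLE vector arrays. It lay below replicate 1 and above replicate 2 in every Snail and Twist group, and below both in the vector groups of both lines. The fits with the number as a block are given with the alternatives. Of the 100 genes highest on this axis, in the direction of HMLE Twist replicate 1, 50 were small RNAs, which made up 2.172% of the genes tested. Genes at the opposite end were not looked at.

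The arrays labelled MCF10A Twist shared 563 genes with the difference of HMLE and MCF10A vector arrays, 251 higher and 312 lower, where independent lists would share 31.77 and 29.72. Both used the same MCF10A vector arrays. Their group mean correlated across genes at 0.979 with HMLE Twist, 0.965 with HMLE Snail, 0.946 with MCF10A Snail, 0.941 with HMLE vector and 0.932 with MCF10A vector arrays.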
